A study of Mus musculus with 6 samples.

How the data were processed

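The series holds 6 RNA sequencing libraries of primary mouse cortical and hippocampal neurons, 2 each of control, HDAC2 knockdown and Sp3 knockdown. Total RNA was extracted with a column kit and libraries were built with an Illumina TruSeq RNA kit, per the labels' protocols. The submitters' processing notes name TopHat, Bowtie, Cuffdiff and the mouse build mm9, without versions. Annotation, strand setting, and whether duplicate or multiply mapped reads were kept are not given in the sources used here.

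The authors deposited a table for each knockdown against control, with 23235 genes. Per the file headers each gene has a locus, a status, an FPKM (fragments scaled to transcript length and mapped fragments) for each group, a log2 fold change, a test statistic, a p-value, a q-value and a call. The FPKM values were made by the authors as 1 value per group, so replicates enter only through their test. The test statistic, a score without fixed range, was deposited by the authors and equals a normal deviate, since the normal two-sided p computed from it lay within 2.79e-06 of the deposited p-value. The deposited q-values lie up to 0.0339 from a Benjamini-Hochberg (BH) adjustment within a table, so the number of tests behind them is not known. Control FPKM is identical in both tables for 100% of genes, so the comparisons share control libraries and scaling. A fold against a group listed at 0 is written in the files as an extreme number. Such genes were counted as called where the authors called them, with no fold given. The HDAC2 table holds 13569 genes with status OK and that for Sp3 holds 13619 such genes, and 81 and 73 of these have a fold against 0. The remaining 9666 and 9616 genes, most of them too low for the authors' test, were not tested.

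Depth per library is unknown, since FPKM keeps no read count. Among genes under 0.3 FPKM in both groups, the most common ratio of Sp3 knockdown to control was 1.62 (48 genes to 3 decimals of log2, against 11 at the next), and that of HDAC2 knockdown to control was 0.939 (19 genes against 7). If these are steps of single fragments, 1 fragment was worth 1.62 times the FPKM in Sp3 knockdown that it was in control. The deposited test statistic has the opposite sign to the fold change, so its sign was reversed here and in the list tests. The precision of each fold is given as a standard error, computed as log2 fold change divided by the reversed statistic. Its median over genes of at least 1 FPKM was 0.26 in the HDAC2 and 0.14 in the Sp3 comparison. Standard errors over 5 were treated as missing, in 7 genes of each table. No standard deviation or number of replicates is attached to any value.

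The following choices were made before the data were examined. Changed genes are those with status OK and q under 0.05 in the authors' deposited table. Fold changes were also centred on their median over genes with at least 1 FPKM in either group, and the shifted statistic was given a normal p and BH adjustment. Centring and upper-quartile scaling were alternatives, and printing centred values in the text was decided after the shift of the median gene was seen. Other alternatives varied the q threshold, a minimum fold change, FPKM filters, the reference distribution, pseudocounts, and the kind and ranking value of the list test. Genes changed in both tables were compared with the product of the list sizes over genes tested and with a one-sided Fisher exact test, beside 100 simulations of unchanged groups with shared control error. The difference between knockdowns was tested per gene as the difference of log2 fold changes over the root of the summed squared standard errors, with a normal p and BH adjustment. The 29 gene lists were tested with cameraPR of limma on the test statistic, at a preset correlation between genes of 0.01 and at 0.05, with BH over the lists of a comparison. No correlation could be estimated without values per library. At 0.05, 4 of 6 lists kept their call in HDAC2 and 7 of 16 in Sp3 knockdown. List medians were also ranked among 10000 random lists matched on mean expression. Lists overlap in some members, and several markers of one cell type are also expressed by others.

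Named genes followed a fixed rule. It takes the targets and paralogs Hdac1, Hdac3, Sp1 and Sp4, the 10 largest rises and falls among called genes with at least 1 FPKM in the higher group and above 0 in the other, and the 4 members with the smallest p of each list that passed or had at least 3 calls. It adds the 8 genes per direction changed in both with the largest smaller test statistic and the 5 per direction with the smallest p of the difference. Clone names were skipped, some genes picked by the rule are not reported here, and the text gives a part of the list members. Coordinates are those of the deposited table, in mm9. The reference annotation at hand is GENCODE M21 on another build, so only its gene names and transcript sequences were used. A B2 repeat copy was taken as 2 markers of 16 bases in order within 120 bases, in either orientation, in any annotated transcript of a gene, and 22706 symbols (97.7%) had a transcript to search.

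The statistics were tested on simulated data, with 200 genes changed by known folds and the tables' own standard errors. Of 50 genes changed by a log2 of 1, centred calls recovered 60% in the HDAC2 simulation over 13364 genes and 82% in the Sp3 simulation over 13261 genes. For a log2 of 0.5 the shares were 12% and 48%, and for a log2 of 2 they were 98% in both. False calls made up 6.3% and 3.5%. The difference test over 13031 genes recovered 36% at a log2 of 1 and 96% at 2, with 0% false calls. These simulations drew normal errors from the same standard errors that the tests divide by, so their shares hold only if those errors are right. For the list test, independent standard normal values were drawn for 13488 genes in place of the deposited statistic. A list shifted by 1 unit was called in 90% of 20 draws, and 0% of the other lists were called. Those draws held no correlation between genes, whereas the list test presets 0.01, so the 0% gives no rate of false list calls for these data. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.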

Results

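RNA sequencing covered 6 libraries of primary mouse cortical and hippocampal neurons. The cultures came from embryos at day 15 and were grown for 17 days. Cytosine arabinoside (AraC), which blocks dividing cells, was added at 1 uM on day 5, and lentivirus carrying short hairpin RNA followed on day 12. The 3 groups of 2 libraries were a control, a knockdown of HDAC2, a class I histone deacetylase found in corepressor complexes, and a knockdown of Sp3, a zinc finger transcription factor that binds GC-rich promoter elements. The series asks whether both proteins regulate a common set of genes. The authors' deposited tables compare each knockdown with the control over 23235 genes, with 1 FPKM value per group and no value per library. No spread per group can therefore be given, and the errors below are the standard errors implied by the authors' test statistic. Total read counts are unknown. Nothing in the labels says that the libraries of a group came from separate cultures, so the p-values may reflect technical spread only. Without values per library, how far the authors' test reflects the spread between these libraries cannot be seen.

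The targeted genes were lower in the libraries named for them. Hdac2 (chromosome 10, 36694349 to 36721694 in mm9 as the file gives it) went from 49.4 to 12.3 FPKM in HDAC2 knockdown in the authors' deposited table, q = 9.22e-14, and its log2 fold change relative to the median gene was -2.32 ± 0.25. Sp3 (chromosome 2, 72774489 to 72827306) went from 15.5 to 5.82 FPKM in Sp3 knockdown in the authors' deposited table, q listed as 0, and its value relative to the median gene was -1.28 ± 0.11. Each target was also measured in the other knockdown. Sp3 stood at 26.7 FPKM in HDAC2 knockdown in the authors' deposited table, q listed as 0, and remained higher relative to the median gene (0.47 ± 0.089, adjusted p = 3.48e-06). Hdac2 stood at 38.8 FPKM in Sp3 knockdown in the authors' deposited table, q = 0.00598, and relative to the median gene the value was -0.22 ± 0.11, adjusted p = 0.101. Of the close paralogs, Hdac1 measured 7.74 FPKM in control and 11.1 in HDAC2 knockdown in the authors' deposited table, q = 0.0993, and Hdac3 measured 60.5 and 58.9, q = 0.931. Sp1 measured 7.82 FPKM in control and 6.43 in Sp3 knockdown in the authors' deposited table, q = 0.0286, with a centred value of -0.15 ± 0.11, adjusted p = 0.276. Sp4 measured 5.65 and 5.17 FPKM in the authors' deposited table, q = 0.431.

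In HDAC2 knockdown, genes of myelin-forming and astrocytic cells were the most strongly raised, and activity-regulated genes and cholesterol synthesis genes were lowered. Gpr17, a receptor of immature oligodendrocytes, rose from 0.649 to 29.1 FPKM in the authors' deposited table, and the astrocytic filament gene Gfap from 16.7 to 167 FPKM. The neuronal activity gene Npas4 fell from 29.4 to 4.02 FPKM in the authors' deposited table, and Arc, which acts in synaptic plasticity, from 49.2 to 8.07 FPKM. The authors' deposited table called 3831 genes at q under 0.05, 3342 higher and 489 lower. The whole distribution was shifted, with a median log2 fold change of 0.32 over genes of at least 1 FPKM, so fold changes below are given relative to that median (centred), as log2 ± standard error. This form was chosen for the text after the shift was seen. Without read counts, a shift made by scaling cannot be told apart from a true rise of most genes, which centring would remove. After centring 1380 genes were higher and 1023 lower, a share of 57.4% higher in place of 87.2%. Of the 1023 lower genes, 486 were called lower in the authors' deposited table.

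Of 19 tested oligodendrocyte lineage markers, 14 were higher and 0 lower at q under 0.05 in the authors' deposited table, 16 and 1 adjusted over the list alone, and 13 and 0 after centring. Their centred median was 1.42, or 0.99 over the 14 members also tested in Sp3 knockdown, and the list passed its test with an adjusted p of 1.93e-16. The myelin genes Mbp (1.45 ± 0.12) and Cnp (1.42 ± 0.15) rose, as did Bcas1 (2.60 ± 0.26). Of 26 tested astrocyte markers, 17 were higher and 0 lower at q under 0.05 in the authors' deposited table, 20 and 0 adjusted over the list alone, and 12 and 0 after centring. The centred median of this list was 1.21, with an adjusted p of 6.23e-06. Its examples were Gfap (3.01 ± 0.37), the water channel gene Aqp4 (2.24 ± 0.27), S100b (2.11 ± 0.29) and the bicarbonate transporter gene Slc4a4 (1.47 ± 0.27). Both glial lists lay above all of 10000 random lists matched on expression, and both kept an adjusted p under 0.05 at a preset correlation of 0.05 (4.73e-10 and 0.00162). Of the 3 microglia and macrophage markers with a test, 1 was called higher in the authors' deposited table, and the list gave an adjusted p of 0.699. Among 11 endothelial, pericyte and meningeal fibroblast markers 6 were called higher in the authors' deposited table, and the list gave an adjusted p of 0.225.

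Of 46 tested activity-regulated genes, 1 were higher and 19 lower at q under 0.05 in the authors' deposited table, 1 and 19 adjusted over the list alone, and 0 and 26 after centring. Their centred median was -0.81 and the adjusted p of the list was 1.84e-19, or 4.97e-09 at a correlation of 0.05. Besides Npas4 (-3.19 ± 0.26) and Arc (-2.92 ± 0.25), the transcription factor genes Fosb (-3.26 ± 0.36) and Egr2 (-2.40 ± 0.26) fell. The glial lists rose in the same libraries. Of 23 tested cholesterol synthesis genes, 0 were higher and 4 lower at q under 0.05 in the authors' deposited table, 0 and 3 adjusted over the list alone, and 0 and 9 after centring. The centred median was -0.70, with an adjusted p of 9.45e-06. Lss (-1.11 ± 0.24), Idi1 (-0.97 ± 0.23) and Fdps (-0.92 ± 0.24), which encode enzymes of the pathway, fell. Of 57 tested protocadherins, 4 were higher and 3 lower at q under 0.05 in the authors' deposited table, 4 and 2 adjusted over the list alone, and 3 and 11 after centring. Their centred median was -0.33, or -0.014 without centring, with an adjusted p of 0.0158 that became 0.299 at a correlation of 0.05. Pcdh8 fell (-0.65 ± 0.059), whereas Pcdh10 (1.31 ± 0.12) and Pcdh11x (1.01 ± 0.28) rose. Of 44 tested genes of the unfolded protein and integrated stress response, 5 were higher and 7 lower at q under 0.05 in the authors' deposited table, 4 and 6 adjusted over the list alone, and 2 and 10 after centring. This list had a centred median of -0.24, which is 0.081 and so on the other side of 0 without centring, and an adjusted p of 0.0272, or 0.299 at a correlation of 0.05. Chac1 (-1.97 ± 0.29) and Edem1 (-1.28 ± 0.24) fell and Atf5 (1.25 ± 0.22) rose.

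Lists of synaptic and channel genes did not pass the list test in HDAC2 knockdown, although single members did. Gabrb2 (1.59 ± 0.42) and Gabbr2 (1.22 ± 0.38), which encode receptor subunits for the inhibitory transmitter GABA, rose, as did the sodium channel subunit gene Scn3b (1.30 ± 0.22), the calcium channel subunit gene Cacnb3 (1.21 ± 0.23), Kcnip4 (1.46 ± 0.24) and the glutamate receptor genes Grin2d (1.23 ± 0.31) and Grin2c (0.93 ± 0.32). Slc17a6, a vesicular glutamate transporter gene (-1.50 ± 0.24), the scaffold gene Shank3 (-1.34 ± 0.29), Cntnap1 (-1.36 ± 0.27) and Prkacb, a catalytic subunit of protein kinase A (-1.51 ± 0.12), fell. For these and the other lists that did not pass, the brackets give members called higher and lower in the authors' deposited table of those tested, and the same adjusted over the list alone. AMPA, kainate and NMDA receptor subunits (6 and 0 of 14, 6 and 0), postsynaptic density scaffolds and signalling (7 and 3 of 30, 7 and 3) and presynaptic vesicle and active zone (7 and 2 of 39, 7 and 2) did not pass. GABA and glycine receptors and inhibitory synapse (5 and 0 of 22, 5 and 0), synaptic adhesion molecules (6 and 1 of 42, 5 and 1) and voltage-gated sodium and calcium channels (5 and 0 of 22, 5 and 0) did not pass. Potassium and HCN channels (18 and 2 of 55, 18 and 2), long-term potentiation and memory signalling (10 and 1 of 48, 9 and 1) and dendrite, axon and cytoskeleton genes (9 and 1 of 44, 8 and 1) did not pass. Histone deacetylases and their corepressor complexes (12 and 2 of 38, 13 and 3), Sp and KLF family transcription factors (4 and 0 of 17, 4 and 0) and glutamatergic neuron markers (5 and 1 of 20, 5 and 1) did not pass. GABAergic neuron markers (8 and 1 of 23, 10 and 1), neural progenitor and cell cycle genes (8 and 0 of 35, 8 and 0) and interferon-stimulated and double-stranded RNA response genes (10 and 1 of 19, 10 and 1) did not pass. The p53 response and apoptosis (6 and 1 of 33, 6 and 1), heat shock proteins and chaperones (3 and 0 of 32, 1 and 0) and oxidative phosphorylation subunits (10 and 1 of 75, 7 and 1) did not pass. Cytosolic ribosomal proteins (11 and 0 of 78, 3 and 0), glycolysis and hypoxia (5 and 0 of 32, 4 and 0) and proteasome subunits (1 and 0 of 31, 0 and 0) did not pass. The adjusted p of these lists, in the same order, was 0.733, 0.586, 0.586, 0.734, 0.734, 0.734, 0.734, 0.62, 0.733, 0.586, 0.734, 0.954, 0.789, 0.734, 0.586, 0.812, 0.586, 0.722, 0.657, 0.812 and 0.699. Examples of members of these lists that passed the threshold both with and without centring, among others, were Neurod1 (1.58 ± 0.30), Sox2 (1.06 ± 0.26), Prom1 (1.51 ± 0.17), B2m (2.17 ± 0.26), Ifitm3 (3.04 ± 0.75), Apaf1 (1.01 ± 0.090), Cryab (2.25 ± 0.36), Car9 (3.92 ± 0.62) and Gatad2a (0.94 ± 0.15), all higher, and Cck (-1.36 ± 0.23), Btg2 (-1.50 ± 0.24), Rac1 (-1.45 ± 0.26), Xaf1 (-1.73 ± 0.28) and Sap18 (-1.90 ± 0.26), all lower. In Sp3 knockdown Btg2 (-1.26 ± 0.12), Rac1 (-0.47 ± 0.14), Xaf1 (-1.91 ± 0.19) and Sap18 (-2.33 ± 0.16) were lower too, and Cck was higher (0.62 ± 0.10). Sap18 was more than 1.5 log2 lower in both knockdowns before centring and so belongs to the group of such genes examined below. B2m, Ifitm3 and Xaf1 belong to the interferon list, of which 10 members were called higher and only Xaf1 lower in the authors' deposited table. The fall of Xaf1 was shared with Sp3 knockdown, and so was the rise of B2m (1.31 ± 0.19 in Sp3 knockdown).

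The 10 largest rises in HDAC2 knockdown were Atp2a3 (6.07 ± 1.14), Mag (5.97 ± 1.44), Enpp6 (5.39 ± 1.20), S100a4 (5.25 ± 1.05), Gpr17 (5.17 ± 0.33), Mal (5.13 ± 0.92), Olfml2a (4.60 ± 0.81), Vgll2 (4.53 ± 1.13), Cldn11 (4.42 ± 0.46) and Thbs2 (4.37 ± 0.52). Mag, Mal and Cldn11 encode proteins of myelin. These genes were near the floor in control, at 0.0373 to 0.649 FPKM in the authors' deposited table, so the size of their folds rests on few reads. The 10 largest falls were Amd1 (listed together with Amd2, -4.34 ± 0.57), Vmn2r-ps129 (-3.47 ± 0.29), Fosb, Npas4, Nanog (-3.13 ± 0.28), Pramel4 (-2.99 ± 0.30), Tapbpl (-2.94 ± 0.25), Arc, H2-T23 (-2.91 ± 0.27) and Omd (-2.76 ± 0.25). Of these, Vmn2r-ps129, Nanog, Pramel4, Tapbpl, H2-T23 and Omd were lower by a similar amount in Sp3 knockdown. Fosb (-1.30 ± 0.17), Arc (-0.94 ± 0.13), Npas4 (-0.68 ± 0.11) and Amd1 (-0.42 ± 0.15) were lower in Sp3 knockdown too, but by less. Annotated transcripts of Nanog, Tapbpl, H2-T23 and Omd hold a copy of the B2 repeat. Near-identical copies share reads, so values of Amd1, H2-T23 and the ribosomal protein genes are uncertain.

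In Sp3 knockdown, genes of synaptic adhesion, of presynaptic terminals and of cholesterol synthesis were higher, and genes of dividing cells and of the oligodendrocyte lineage were lower. The synaptic adhesion gene Nlgn1 rose from 45.4 to 70.2 FPKM in the authors' deposited table, and Gabbr2, a member of the GABA and glycine receptor list, from 27.8 to 89.2 FPKM. Cenpf, which acts in mitosis, fell from 7.75 to 2.47 FPKM in the authors' deposited table, and Sox10, a transcription factor gene of the oligodendrocyte lineage, from 4.21 to 1.52 FPKM. Whether the share of cell types differed between Sp3 knockdown and control was not tested, and values of whole cultures cannot separate it from a change within cells. The authors' deposited table called 5353 genes, 1801 higher and 3552 lower. The median log2 fold change over genes of at least 1 FPKM was -0.13, and after centring on it 2736 genes were higher and 2383 lower, a share of 53.4% higher in place of 33.6%. The implied standard error of a log2 fold change had a median of 0.14, against 0.26 in the HDAC2 comparison, so smaller changes were called here.

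Of 41 tested synaptic adhesion molecules, 18 were higher and 1 lower at q under 0.05 in the authors' deposited table, 18 and 1 adjusted over the list alone, and 23 and 0 after centring. Their centred median was 0.39 and the adjusted p was 8.34e-08, or 9.91e-04 at a correlation of 0.05. Nlgn1 (0.76 ± 0.045), Cdh9 (1.61 ± 0.12), Cdh8 (1.12 ± 0.084) and Lrrtm2 (1.05 ± 0.098) rose. Of 40 tested presynaptic genes, 15 were higher and 2 lower at q under 0.05 in the authors' deposited table, 15 and 3 adjusted over the list alone, and 21 and 0 after centring. This list had a centred median of 0.38 and an adjusted p of 1.01e-04, or 0.0142 at a correlation of 0.05, with Amph (1.22 ± 0.10), Rims1 (0.69 ± 0.055) and Cplx2 (1.22 ± 0.15) as examples. Of 22 tested sodium and calcium channel genes, 8 were higher and 2 lower at q under 0.05 in the authors' deposited table, 8 and 3 adjusted over the list alone, and 11 and 0 after centring. The centred median was 0.31, with an adjusted p of 4.49e-05, or 0.00416 at a correlation of 0.05. Scn3b (1.65 ± 0.069) and Cacnb4 (0.98 ± 0.068) rose. Of 55 tested potassium and HCN channel genes, 24 were higher and 8 lower at q under 0.05 in the authors' deposited table, 25 and 9 adjusted over the list alone, and 30 and 5 after centring. Here the adjusted p was 0.00296, or 0.0757 at a correlation of 0.05, and the centred median 0.31. Kcnip4 (1.71 ± 0.21) and Kcns2 (1.12 ± 0.14) rose, and Kcnj10, a potassium channel gene of glial cells, fell (-2.04 ± 0.13).

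Of 22 tested GABA and glycine receptor genes, 7 were higher and 5 lower at q under 0.05 in the authors' deposited table, 9 and 5 adjusted over the list alone, and 10 and 3 after centring (centred median 0.18, adjusted p = 0.0123, or 0.0757 at a correlation of 0.05). Gabbr2 (1.81 ± 0.11) and Gabrb2 (1.72 ± 0.12) led this list. Of 15 tested AMPA, kainate and NMDA receptor subunits, 7 were higher and 2 lower at q under 0.05 in the authors' deposited table, 7 and 2 adjusted over the list alone, and 7 and 1 after centring (centred median 0.28, adjusted p = 0.0134, or 0.0707 at a correlation of 0.05). The kainate receptor gene Grik4 (1.18 ± 0.15) and Gria4 (0.57 ± 0.063) rose. Of 44 tested dendrite, axon and cytoskeleton genes, 10 were higher and 8 lower at q under 0.05 in the authors' deposited table, 11 and 9 adjusted over the list alone, and 14 and 6 after centring (centred median 0.25, adjusted p = 0.0142, or 0.132 at a correlation of 0.05). The guidance gene Slit2 (1.26 ± 0.10) rose and Cdc42 (-0.78 ± 0.073) fell. Of 57 tested protocadherins, 16 were higher and 4 lower at q under 0.05 in the authors' deposited table, 16 and 4 adjusted over the list alone, and 23 and 2 after centring (centred median 0.25, adjusted p = 4.18e-04, or 0.049 at a correlation of 0.05), with Pcdh10 (1.07 ± 0.048) and Pcdh17 (1.31 ± 0.13) higher. Genes with long loci tended to be higher in Sp3 knockdown, with a Spearman rho across genes of 0.15 between fold change and locus span, against 0.031 in HDAC2 knockdown. Against random lists matched also on locus span, the list medians stood at percentiles of 52.1 for the GABA and glycine receptors, 74.7 for the AMPA, kainate and NMDA receptors, 92.4 for the sodium and calcium channels, 94.95 for the protocadherins and 97.2 for the dendrite, axon and cytoskeleton list, in place of 90.0, 97.53, 99.5, 99.99 and 99.8. The synaptic adhesion list stood at 99.73 and the presynaptic list at 99.97.

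Of 23 tested cholesterol synthesis genes, 10 were higher and 0 lower at q under 0.05 in the authors' deposited table, 10 and 0 adjusted over the list alone, and 14 and 0 after centring (centred median 0.40, adjusted p = 1.54e-04, or 0.00984 at a correlation of 0.05). Nsdhl (0.92 ± 0.10), Fdps (0.83 ± 0.12), Tm7sf2 (0.82 ± 0.098) and Mvk (0.78 ± 0.097) rose. Of 24 tested GABAergic neuron markers, 11 were higher and 3 lower at q under 0.05 in the authors' deposited table, 11 and 3 adjusted over the list alone, and 12 and 3 after centring (centred median 0.47, adjusted p = 0.00525, or 0.0646 at a correlation of 0.05). Calb2 (1.25 ± 0.11) and the neuropeptide gene Sst (1.07 ± 0.10) rose and Sox6 fell (-0.79 ± 0.081). Of 31 tested proteasome subunits, 8 were higher and 2 lower at q under 0.05 in the authors' deposited table, 8 and 2 adjusted over the list alone, and 13 and 1 after centring (centred median 0.23, adjusted p = 0.0192, or 0.131 at a correlation of 0.05). Psmb2 (0.61 ± 0.10) rose and Psmc4 (-0.48 ± 0.11) fell.

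Of 35 tested neural progenitor and cell cycle genes, 0 were higher and 29 lower at q under 0.05 in the authors' deposited table, 0 and 31 adjusted over the list alone, and 0 and 27 after centring (centred median -0.64, adjusted p = 1.52e-08, or 3.45e-04 at a correlation of 0.05). Cenpf (-1.52 ± 0.13), the mitotic cyclin gene Ccnb1 (-0.89 ± 0.13), the replication gene Mcm6 (-0.79 ± 0.12) and Sox2 (-0.73 ± 0.11) fell. Of 14 tested oligodendrocyte lineage markers, 0 were higher and 11 lower at q under 0.05 in the authors' deposited table, 0 and 11 adjusted over the list alone, and 0 and 11 after centring (centred median -0.62, adjusted p = 0.00136, or 0.0142 at a correlation of 0.05). Sox10 (-1.33 ± 0.25), Cnp (-1.14 ± 0.16) and the receptor gene Pdgfra (-0.93 ± 0.12) fell. Of 27 tested astrocyte markers, 4 were higher and 9 lower at q under 0.05 in the authors' deposited table, 6 and 10 adjusted over the list alone, and 8 and 8 after centring, and the list gave an adjusted p of 0.568. Gfap (-0.73 ± 0.12) and Sox9 (-0.89 ± 0.13) fell in this list. Of 33 tested genes of the p53 response and apoptosis, 3 were higher and 19 lower at q under 0.05 in the authors' deposited table, 3 and 20 adjusted over the list alone, and 4 and 15 after centring (centred median -0.39, adjusted p = 0.00357, or 0.0646 at a correlation of 0.05). Trp53inp1 (-0.85 ± 0.068) and Mcl1 (-0.96 ± 0.13) fell and Ei24 (0.86 ± 0.081) rose. Of 46 tested activity-regulated genes, 5 were higher and 21 lower at q under 0.05 in the authors' deposited table, 5 and 22 adjusted over the list alone, and 7 and 19 after centring (centred median -0.25, adjusted p = 0.0106, or 0.122 at a correlation of 0.05). Fos (-0.95 ± 0.12), Jun (-1.09 ± 0.12) and Btg2 (-1.26 ± 0.12) fell and the neurotrophin gene Bdnf rose (0.65 ± 0.060). Of 78 tested cytosolic ribosomal protein genes, 0 were higher and 34 lower at q under 0.05 in the authors' deposited table, 0 and 36 adjusted over the list alone, and 1 and 10 after centring (centred median -0.22, adjusted p = 0.0192, or 0.222 at a correlation of 0.05), with Rps16 (-0.50 ± 0.11) and Rps19 (-0.66 ± 0.16) lower.

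The remaining lists in Sp3 knockdown follow in the same form, with members called higher and lower in the authors' deposited table of those tested, and the same adjusted over the list alone. Postsynaptic density scaffolds and signalling (7 and 8 of 31, 7 and 8), long-term potentiation and memory signalling (13 and 10 of 48, 14 and 10) and histone deacetylases and their corepressor complexes (4 and 11 of 38, 4 and 11) did not pass. Sp and KLF family transcription factors (2 and 3 of 17, 2 and 3), glutamatergic neuron markers (5 and 4 of 20, 6 and 4) and microglia and macrophage markers (1 and 1 of 4, 1 and 2) did not pass. Endothelial, pericyte and meningeal fibroblast markers (1 and 5 of 10, 2 and 5), interferon-stimulated and double-stranded RNA response genes (2 and 3 of 16, 2 and 4) and unfolded protein and integrated stress response (8 and 18 of 44, 9 and 19) did not pass. Heat shock proteins and chaperones (2 and 11 of 32, 2 and 11), oxidative phosphorylation subunits (8 and 11 of 75, 7 and 8) and glycolysis and hypoxia (3 and 7 of 32, 3 and 7) did not pass. The adjusted p of these lists, in the same order, was 0.752, 0.0893, 0.45, 0.762, 0.0959, 0.836, 0.836, 0.836, 0.398, 0.195, 0.588 and 0.961. The 10 largest rises were C1s (2.96 ± 0.68), Kirrel2 (2.56 ± 0.39), Casp1 (2.51 ± 0.55), Aldh1a3 (2.21 ± 0.43), Ablim3 (2.10 ± 0.14), Fst (2.07 ± 0.26), Psg16 (2.04 ± 0.29), the netrin receptor gene Unc5a (1.99 ± 0.11), Cdh13 (1.97 ± 0.12) and Smoc2 (1.97 ± 0.31). The 10 largest falls were Vmn2r-ps129 (-3.87 ± 0.21), Slc35d2 (-3.41 ± 0.34), Bdkrb2 (-3.26 ± 1.22), Omd (-3.23 ± 0.16), Nanog (-3.23 ± 0.19), Pramel4 (-3.20 ± 0.26), H2-T23 (-3.07 ± 0.18), Ugt1a6a (-3.03 ± 0.84), Tapbpl (-3.03 ± 0.16) and Ugt1a6b (-2.99 ± 0.73). In the authors' deposited table C1s, Kirrel2, Casp1, Aldh1a3 and Smoc2 were at 0.186 to 0.856 FPKM in control, and Slc35d2, Bdkrb2, Ugt1a6a and Ugt1a6b at 0.111 to 0.683 in Sp3 knockdown, so the size of these folds rests on few reads. The Ugt1a6 pair overlaps and shares sequence, so its values are uncertain.

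**Figure D1:**
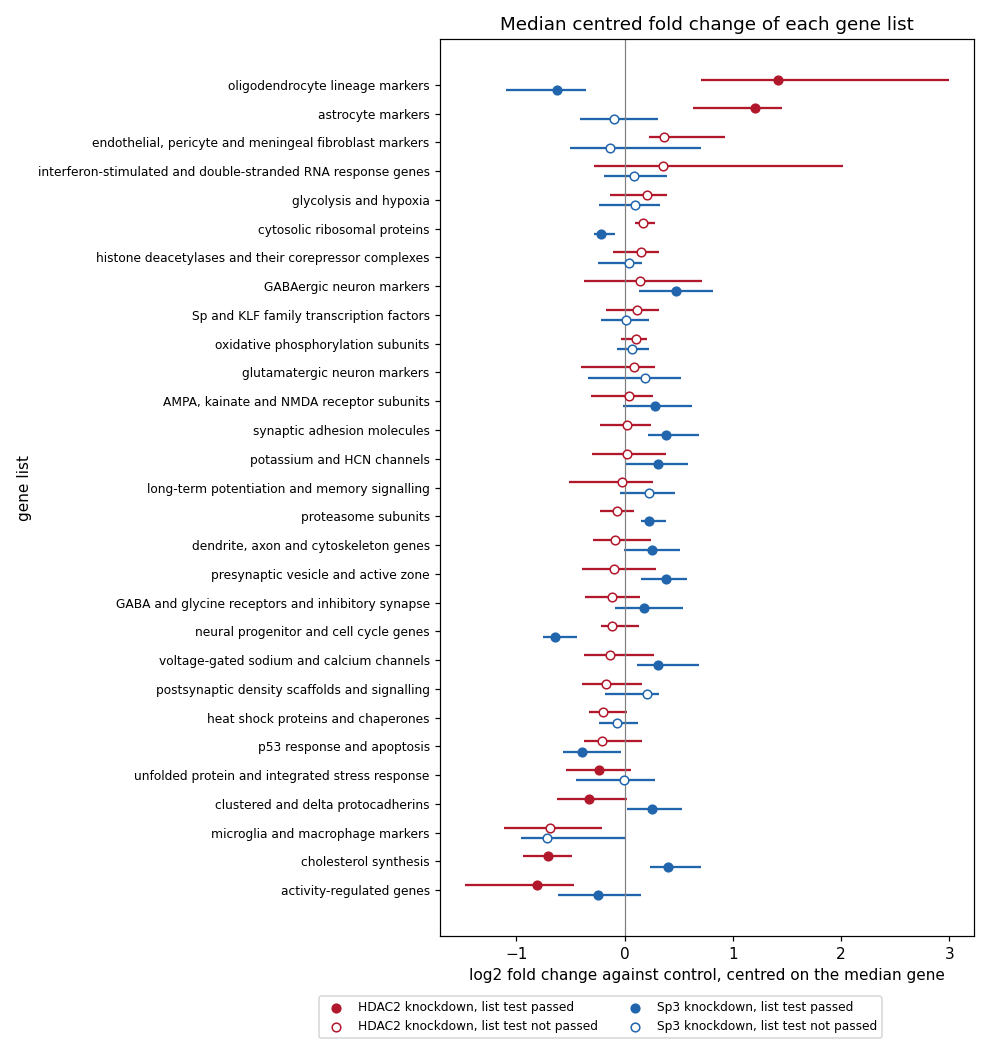
Median log2 fold change against control of the tested members of each of the 29 gene lists, centred on the median gene, in HDAC2 knockdown (red) and Sp3 knockdown (blue). Lines run from the lower to the upper quartile of the members, and filled points mark lists that passed the list test. The oligodendrocyte list lies at 1.42 in HDAC2 knockdown (0.99 over the 14 members tested in both) and -0.62 in Sp3 knockdown, and the cholesterol synthesis list at -0.70 and 0.40.

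Genes changed in both knockdowns address whether HDAC2 and Sp3 share a gene set. Zmiz2 (0.83 ± 0.069 in HDAC2 and 0.78 ± 0.059 in Sp3 knockdown), Runx1t1 (1.19 ± 0.10 and 1.30 ± 0.087), Pcdh10 (1.31 ± 0.12 and 1.07 ± 0.048) and Rnft2 (1.12 ± 0.12 and 1.57 ± 0.066) were among the 8 genes most firmly higher in both. The others were Fam49a (0.52 ± 0.061 and 0.94 ± 0.049), Zfand2a (1.22 ± 0.15 and 1.12 ± 0.077), Tmco1 (2.09 ± 0.24 and 1.44 ± 0.12) and Csnk1g2 (1.22 ± 0.16 and 1.20 ± 0.083). The 8 most firmly lower in both were Irak1 (-2.20 ± 0.14 and -2.65 ± 0.075), Nip7 (-2.15 ± 0.16 and -2.35 ± 0.15), Prkacb (-1.51 ± 0.12 and -0.88 ± 0.091), Vmn2r-ps129, Tapbpl, Nanog, Omd and H2-T23, of which Irak1, Nip7, Tapbpl, Nanog, Omd and H2-T23 hold a B2 copy in an annotated transcript. Of synaptic and channel genes, Scn3b, Gabrb2, Gabbr2 and Kcnip4 were higher in both, with the values given above, and so was Cdh8 (0.56 ± 0.11 and 1.12 ± 0.084).

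Among 13357 genes tested in both tables, 859 were called higher in both and 306 lower in both. Independent lists of the same sizes would share 416.2 and 128, and a one-sided Fisher exact test gave p = 1.35e-137 and p = 9.84e-67 across genes, which are not independent replicates. Another 653 genes were higher in HDAC2 and lower in Sp3 knockdown, where 835.3 would be shared, and 31 were lower in HDAC2 and higher in Sp3 knockdown, where 63.8 would be. After centring 527 genes were higher in both and 462 lower in both, against 251.1 and 179.9. In 100 simulations of unchanged groups that share the control error, with a correlation of errors of 0.5, 122.5 genes on average went the same way in both at unadjusted p under 0.05. The number was 66.4 with the control error taken from the smaller standard error, and the tables held 1615. Such simulations do not show how much the shared controls add among genes that do change. Part of the excess may come from the shared control libraries, which cannot be split without values per library. The genes lower in both also include 58 genes more than 1.5 log2 lower in both knockdowns. Their fall may come from reads of B2 repeat RNA or from the shared controls, as described below, and the overlap was not tested without them.

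Across 13187 genes with at least 1 FPKM in some group, the fold changes of the knockdowns had a Pearson r of 0.34 and a Spearman rho of 0.29. Genes are not independent replicates, so this describes the tables. Over the 13179 of these genes with usable standard errors the observed covariance was 0.119, beside 0.0514 simulated for unchanged groups sharing controls, and the observed r was 0.378. The simulated r depends on the assumed control error. It was 0.471, above the observed value, with a correlation of errors of 0.5, and 0.354, below it, with the control error taken from the smaller standard error. The share of genes with the same sign was 49.5%, or 59.6% after centring, beside 66.7% and 59.9% in the simulations.

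**Figure D2:**
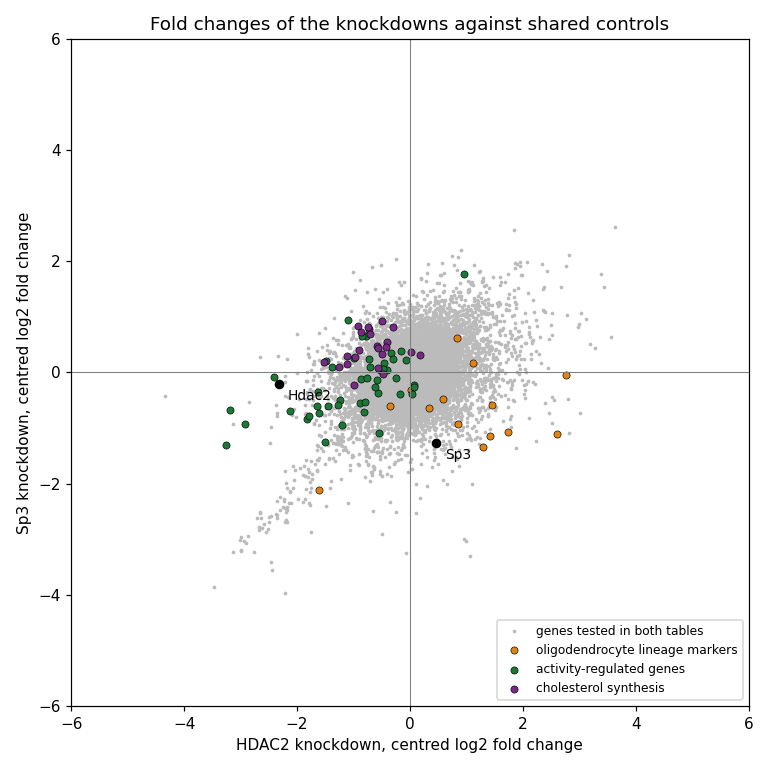
Centred log2 fold change of each gene in HDAC2 knockdown (horizontal axis) and Sp3 knockdown (vertical axis), for 13187 genes tested in both tables (grey), with 3 gene lists in colour and both targets in black. Axes run from -6 to 6 and 4 genes lie outside them. A narrow group of genes runs to the lower left, and most oligodendrocyte markers lie to the right of 0 and below it.

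The knockdowns also differed from each other. The 5 genes most firmly higher in HDAC2 than in Sp3 knockdown were Sp3 itself, Erbb2ip (0.85 ± 0.081 and -0.73 ± 0.074), the actin-binding gene Gsn (1.79 ± 0.11 and -0.98 ± 0.15), the RNA-binding gene Qk (0.56 ± 0.10 and -0.78 ± 0.055) and Gng12 (0.69 ± 0.094 and -0.79 ± 0.10), with values for HDAC2 and Sp3 knockdown in that order. The 5 most firmly lower were Adora1, an adenosine receptor gene (-1.01 ± 0.096 and 0.69 ± 0.056), Klc2 (-1.19 ± 0.12 and 0.71 ± 0.064), Hs6st2 (-0.72 ± 0.11 and 0.90 ± 0.063), Elavl4 (-1.06 ± 0.10 and 0.43 ± 0.067) and Bdnf (-0.78 ± 0.097 and 0.65 ± 0.060). The test of the difference called 3815 of 13277 genes, 3528 higher and 287 lower in HDAC2 knockdown. After centring it called 1043 higher and 912 lower. Among the lists, the median of the centred differences per gene was -1.25 for cholesterol synthesis (adjusted p = 1.99e-14), with all 23 members tested in both lower in HDAC2 knockdown. It was 1.43 for the oligodendrocyte lineage (adjusted p = 2.10e-16) with all 14 members higher, and 1.32 for astrocyte markers (adjusted p = 2.19e-07) with 25 of 26 higher. Activity-regulated genes were lower in HDAC2 than in Sp3 knockdown by a median of -0.69 (adjusted p = 7.18e-13), in 41 of 46 members. Errors of shared controls were not subtracted, which makes the test per gene conservative. The list tests compare members with the other genes, so this need not hold for their adjusted p.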

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

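Of the tests in this part, the one on B2 copies outside the group of 58 genes was chosen before its result was seen, although the excess of copies within the group had been seen. The tests on scaling, glial share, shared controls and dilution were chosen after their results, or values close to them, were seen.

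The centred fold changes of the knockdowns were tested against each other for the lists and named genes, and the results that passed both with and without centring are given as centred HDAC2 minus Sp3 knockdown. Lists higher in HDAC2 knockdown were astrocyte markers 1.32, oligodendrocyte lineage markers 1.43, neural progenitor and cell cycle genes 0.61 and cytosolic ribosomal proteins 0.36 (medians of the log2 differences per gene). Lists lower in HDAC2 knockdown were presynaptic vesicle and active zone -0.44, synaptic adhesion molecules -0.50, voltage-gated sodium and calcium channels -0.61, activity-regulated genes -0.69, clustered and delta protocadherins -0.59, cholesterol synthesis -1.25 and proteasome subunits -0.44. At a preset correlation of 0.05 the differences of the sodium and calcium channels (adjusted p = 0.0847), the ribosomal proteins (0.254) and the proteasome subunits (0.158) no longer passed, and of all 29 lists 8 passed in place of 14. Named genes higher in HDAC2 than in Sp3 knockdown, by log2 difference, were Ugt1a6a 4.03, Ugt1a6b 3.95, Gfap 3.74, Bcas1 3.70, S100b 2.93, Rps27 2.84, Gsn 2.77, Sox10 2.63, Cnp 2.56, Kcnj10 2.33 and Grin2c 2.06. After these came Mbp 2.03, Prom1 1.99, Gja1 1.95, Aqp4 1.85, Pdgfra 1.79, Sox2 1.79, Sp3 1.75, Sox6 1.64, Erbb2ip 1.57, Fn1 1.54 and Gng12 1.48. Then followed Aldoc 1.47, Cryab 1.42, Dnajb9 1.36, Qk 1.35, Sox9 1.32, Slc16a3 1.29, Egln3 1.27, Mcl1 1.27, Slc4a4 1.20, Ndufs5 1.11 and Atf5 1.11. Smaller differences were found for Neurod1 1.06, Mta2 0.98, Cdc42 0.97, Cspg4 0.97, Cacnb3 0.92, Rorb 0.91, Hspa13 0.90, Gabrd 0.89, Gatad2a 0.89, Phgdh 0.87 and Rps16 0.81. The smallest were Cenpf 0.80, Pax6 0.80, Tpx2 0.69, Trp53inp1 0.64, Pcdh15 0.53, Irak1 0.45 and Fau 0.35. Named genes lower in HDAC2 than in Sp3 knockdown were Amd1 (listed with Amd2) -3.92, Npas4 -2.51, Egr2 -2.32, Psg16 -2.28, Hdac2 -2.10, Arc -1.99, Cck -1.98, Fosb -1.96, Klc2 -1.90, Fdps -1.75 and Adora1 -1.71. Next in this direction came Calb2 -1.64, Hs6st2 -1.62, Slc17a6 -1.59, Mvk -1.51, Chac1 -1.49, Elavl4 -1.49, Bdnf -1.43, Nsdhl -1.41, Cdh13 -1.41, Lss -1.39 and Sst -1.36. The smallest of these were Ablim3 -1.36, Bhlhe22 -1.33, Cntnap1 -1.25, Idi1 -1.25, Edem1 -1.17, Cdh9 -1.12, Tm7sf2 -1.11, Cacnb4 -1.08, Pcdh19 -1.05, Pcdh8 -0.89 and Atp5g1 -0.22. The difference of Atp5g1 has the other sign without centring (log2 fold change of 0.36 in HDAC2 and 0.14 in Sp3 knockdown in the authors' deposited table), so its direction depends on the centring.

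A group of 58 genes was more than 1.5 log2 lower in both knockdowns, with a median of 49.97 FPKM in control, 9.80 in HDAC2 and 6.72 in Sp3 knockdown over the authors' deposited table. The threshold was set after seeing the data, and a sequence search of these genes pointed to the B2 repeat, a short interspersed element with many transcribed copies. Of the 56 genes with a searchable transcript 24 held a B2 copy, where expression-matched random sets held 1.4 on average and at most 7, and outside the group 252 carriers were lower than the other of 12817 genes in both tables (carriers minus others -0.11 in HDAC2 knockdown, permutation p = 0.0011, and -0.15 in Sp3 knockdown, permutation p = 1e-05, the smallest that permutations can give). The excess within the group had pointed to the repeat, so it cannot count as a test of it. The shift of carriers outside the group would follow if more reads of B2 RNA were assigned to carriers in the control libraries. That shift was small beside the fall of more than 1.5 log2 within the group. Chance high values in the shared controls stay open, since the median difference between the knockdowns over the group (0.13) decides little in genes chosen for being low in both, and so do the 32 genes without a detected copy and a change in B2 RNA caused by either knockdown, which was not tested.

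Scaling does not account for the higher astrocyte and oligodendrocyte markers in HDAC2 knockdown, since the smaller of the centred list medians was 1.21, above all random lists. Of the 10 most abundant astrocyte markers 10 lay above 0 after centring, among them Fabp7 (704 to 1426 FPKM in the authors' deposited table), Apoe (711 to 1313) and Slc1a3 (173 to 721), although these 3 had wide errors and were not called singly. With the lower quartile of the whole list already at 0.63, this count does not separate a higher share of glial cells from a change within them. Several astrocyte markers are also expressed by neural progenitors, and the microglia list, with 3 tested genes, was not higher (centred median -0.69). More glial cells, through culture or through the knockdown, and a change within glial cells both stay open, as only the group labels separate these libraries.

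Activity-regulated genes were lower in HDAC2 knockdown. Shared controls do not account for all of this, because the list was lower in HDAC2 than in Sp3 knockdown (adjusted p = 7.18e-13). Dilution by glial RNA would lower other neuronal genes too. The dendrite, axon and cytoskeleton list had a centred median of -0.084 (bootstrap interval -0.18 to 0.11, median above 0 without centring), against -0.81 for the activity-regulated list. Other lists went both ways, with centred medians of -0.33 for protocadherins, -0.17 for postsynaptic density genes, 0.087 for glutamatergic and 0.14 for GABAergic neuron markers. None of these lists fell as far as the activity-regulated list. Their members can be expressed by other cells too, so a part played by dilution stays open. An effect of HDAC2 on the activity-regulated genes, and a difference in the activity of the cultures, also stay open, as only the group labels separate these libraries. The smaller fall in Sp3 knockdown cannot be told apart from chance high values in the shared controls, as the list fell further in HDAC2 knockdown, by a median difference of -0.69.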

How the results depend on the processing

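The centred difference, the centred list statistic, the matching on locus span, the second control error and the correlation without the 58 genes were chosen after seeing the data. No paired analysis was possible because the deposited tables hold 1 value per group, and for the same reason leaving out each replicate and the fit with a replicate block were not run. Depth is unknown, so counting error of low genes was not separated from other error.

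Centring gave 2403 changed genes in HDAC2 knockdown (1380 higher, 1023 lower) and 2736 higher in Sp3 knockdown, and upper-quartile scaling 2409 (1397 higher, 1012 lower) in HDAC2 knockdown. Both shift all fold changes of a table, which by construction moves these counts. Genes higher in both numbered 527 with centring and 483 with upper-quartile scaling, genes lower in both 462 and 505, genes higher in HDAC2 and lower in Sp3 knockdown 163 and 199, and the reverse 143 and 105. At q under 0.01 there were 324 genes lower in HDAC2 knockdown, 766 changed the same way in both, 553 higher in both, 342 higher in HDAC2 and lower in Sp3, and 15 the reverse. A minimum log2 fold change of 0.5 left 3106 genes in Sp3 knockdown (938 higher, 2168 lower), 735 changed the same way in both, 494 higher in both, 382 higher in HDAC2 and lower in Sp3, and 10 the reverse. Both settings are stricter by construction. The other filters and thresholds kept each count within 1.5 times.

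The difference test called 5958 genes (5464 higher, 494 lower) when 0.5 times the product of the standard errors was taken as shared, which narrows its errors, and 1955 (1043 higher, 912 lower) with centring. The correlation was 0.20 over genes called in neither table, 0.29 without the 58 genes, and 0.34 to 0.38 under the other settings. With the control error taken from the smaller standard error, the simulated covariance was 0.0386 and the simulated r 0.354, so that the observed 0.378 lay above it and not below as with a correlation of errors of 0.5. At a preset correlation of 0.05, 7 lists kept their call in Sp3 knockdown, as the test is wider by construction. By counts of calls (Fisher exact test) 2 of 6 lists in HDAC2 and 3 of 16 in Sp3 knockdown no longer passed, by log2 fold change as ranking value 0 and 4, and by rank 0 and 1. Against lists matched on span 5 of 16 lists in Sp3 knockdown lay within the middle 95 percent, of which the GABA and glycine receptors did so already with matching on expression alone, and with the centred statistic all 6 and 16 lists still passed. With 1 FPKM added, 34 named genes in HDAC2 and 31 in Sp3 knockdown moved by more than their standard error. Ndufs1, called lower in Sp3 knockdown, moved from a log2 fold change of -0.13 in the authors' deposited table to 0.0039 with centring, and the difference of Atp5g1 between the knockdowns turned with it.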

Other observations

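The values in this part were chosen after they were seen, and no explanation was tested for them.

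Several very abundant genes differed widely in FPKM between groups, although of those in this paragraph only Mir5109, in Sp3 knockdown, passed the authors' test. In the authors' deposited table Gm20594 stood at 81978 FPKM in control, 108439 in HDAC2 and 64007 in Sp3 knockdown. Lars2 stood at 3959, 8233 and 1256 FPKM in the authors' deposited table, and Mir5109 at 5165, 11705 and 1457. Rn45s stood at 7438 FPKM in control and 3095 in Sp3 knockdown in the authors' deposited table, and its HDAC2 value is listed at 0 with a status that marks too many fragments to process. The actin gene Actb followed the median gene, with a log2 fold change of 0.32 in HDAC2 and -0.13 in Sp3 knockdown in the authors' deposited table.

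Rpl26 had 43.8 FPKM in control, 298 in HDAC2 and 0.00855 in Sp3 knockdown in the authors' deposited table, where the last comparison had q = 0.763. The ribosomal protein genes have many near-identical pseudogenes, and this value is uncertain. Mir132, a microRNA, had 47.0 FPKM in control and is listed at 0 in both knockdowns in the authors' deposited table, with q = 0.00533 in each. Both comparisons rest on the same control value. FPKM is scaled to transcript length, so in a short gene this value may rest on few fragments, and their number is unknown.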
